A study of Homo sapiens with 6 samples.

How the data were processed

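RNA of 6 samples was hybridised to human whole-transcript arrays, 3 of undifferentiated iPS cells and 3 of MYOG-Venus cells sorted at 3 weeks of myogenic differentiation. Per the labels, biotin-labelled targets were made from total RNA by a double amplification, and sorting gates were set against undifferentiated cultures. The deposited values are on a log2 scale and came from RMA, which corrects background, normalizes quantiles between arrays and summarises probes into probe sets; RMA and R 2.12.1 are named in the submitters' processing notes, and further settings are not given in the sources used here. RMA sets the arrays to nearly 1 distribution, so a change in total RNA per cell cannot be seen, and it compresses differences at low signal. The values carry no detection call, and a fold against a dim group therefore depends on background. The dimmer group averaged under the lowest array median of 4.72 in 372 of the 1827 called genes. Any 2 arrays had identical values in 3.31% to 4.62% of probe sets, and such ties narrow the spread within a group. The value of FGF9 was identical on all 3 MYOG-Venus arrays, and its error rests on the iPS arrays and the pooled spread.

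Groups and replicate numbers were taken from the labels. All 53617 probe sets entered the fit. Array controls were to be left out, but they are not marked in the tables used here, and 3575 probe sets without a name have IDs before the first named one. The annotation table gave 1 gene symbol to 16098 probe sets, several to none of them, and no name to 37519. All 16098 gene IDs matched the reference gene table, whose current symbols were used, and gave 14884 genes. Each gene took the values and call of its probe set with the highest mean over all 6 arrays. 779 genes had several probe sets; calls differed within 83 of these and were opposite in 1. A gene without a named probe set was not analysed here.

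Groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, 2-sided, without covariates, with Benjamini-Hochberg adjustment over all probe sets. The fit had 4 residual and 2.55 prior degrees of freedom. A call needed an adjusted p under 0.05 and at least a 2-fold difference. Differences are MYOG-Venus minus iPS on the log2 scale. The 31 gene lists held 709 distinct genes, of which 453 were measured. They were tested with camera at a preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the lists; camera with an estimated correlation, fry and camera on ranks were run beside it. Camera with an estimated correlation takes its degrees of freedom from the residual ones of the fit, here 4. With few arrays it can therefore lose calls whatever the correlation. Fry asks whether a list's genes move one way on balance and does not set them against other genes. In simulated data with 200 changed probe sets among 53617, the fit of this comparison recovered 87.5% of 72 probe sets changed by 1.5, 96.7% of 61 changed by 2 and 100% of 67 changed by 3 on the log2 scale, and called 1 unchanged probe set. With the cell cycle list raised in simulated values of 14884 genes, camera called it and none of the 30 other lists. Those genes were drawn independently of each other, so the run does not show how camera behaves with correlated genes. Figures were drawn with matplotlib 3.10.9.

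Genes were named by a rule fixed, like the lists, the tests and all but 1 of the alternatives, before the data were examined. The rule took MYOG; the 10 called genes with the largest rise and the 10 with the largest fall, groups not overlapping, without Y-linked genes and XIST; 16 fixed genes; and up to 4 called members of each list with the largest differences, or where under 2 were called the member with the largest difference. It gave 106 measured genes, and a member outside it is named where it completes a small count or is said to be looked up later. The alternatives were the replicate number as a block, median centring, a further quantile normalization, the probe sets above the 50th percentile by mean, a spread model with trend and robust estimation, leaving out each array in turn, no fold minimum, limma's treat against 2-fold, and the mean of a gene's probe sets. A fit of the named probe sets alone was added after the data were seen.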

Results

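Gene expression was measured on 6 whole-transcript arrays of human cells in 2 groups of 3. The first group was undifferentiated induced pluripotent stem (iPS) cells of the line NCRM-1, which were grown feeder-free. The second was sorted from cultures of iPS cells that had been directed to skeletal muscle for 3 weeks without serum, and it was collected by the fluorescence of Venus, a yellow fluorescent protein that reports MYOG, the transcription factor that starts the final differentiation of muscle cells. The labels call the arrays biological replicates without saying which cultures they came from, so the p-values measure the spread between these samples. Each array gave a log2 RMA signal for 53617 probe sets, with array medians of 4.72 to 4.77 and values from 1.99 to 13.96. Across probe sets, which are not independent replicates, arrays of 1 group correlated at r = 0.991 to 0.994 over 6 pairs, and arrays of different groups at r = 0.938 to 0.945 over 9 pairs. The first principal component held 84.3% of the variance and separated the groups. On the second, with 4.58%, MYOG-Venus replicate 3 lay at 36.1 while the other 2 sorted samples lay at −16.8 and −17.8.

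The comparison asked how sorted MYOG-Venus cells differ from the pluripotent state. Of the measured members of lists fixed in advance, 19 of 27 sarcomere genes, 15 of 21 myogenic regulators, 8 of 16 calcium-handling genes, 12 of 27 HOX genes and 8 of 10 matrix genes rose in limma. The 15 regulators include MYOG, the gene of the sorted reporter. On the other side, 19 of 27 pluripotency genes, 8 of 15 epithelial markers and 12 of 35 cell cycle genes fell. Of 14884 named genes, 830 rose (5.58%) and 997 fell (6.70%) by at least 2-fold at an adjusted p under 0.05 in limma. Without MYOG-Venus replicate 3, the array that stood apart, 815 rose and 1077 fell. The balance turned with quantile normalization applied again, to 898 higher and 839 lower, and with limma's treat against 2-fold, to 469 and 417. 51 genes rose and 29 fell by at least 16-fold. Over all probe sets, 4615 were called (8.61%), 2030 higher and 2585 lower, and 2711 of these carry no gene name here. The median difference over all probe sets was 0.004 on the log2 scale.

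MYOG, read by probe set 16698159, rose from 5.91 ± 0.21 in iPS cells to 10.11 ± 0.14 in sorted cells (log2 signal, mean ± SD, n = 3). That is 18.4-fold, or 4.20 on the log2 scale with a standard error of 0.13 (adjusted p = 3.18e-06). Since the cells were sorted on this gene's reporter, its rise checks the labels and is no finding of the comparison.

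The largest rise was in KLHL41 (probe set 16887278), a kelch protein that stabilises the thin filament protein nebulin. Its signal went from 3.15 ± 0.021 to 10.70 ± 0.14, 188-fold higher (adjusted p = 1.66e-07). NEB, which encodes nebulin itself, rose 45.0-fold. Next came LUM, a small proteoglycan of collagen matrix, at 119-fold, and CASQ2, a calcium-binding protein of the sarcoplasmic reticulum, at 92.0-fold. The receptor tyrosine kinase EPHA3 rose 63.5-fold, the transcriptional coactivator EYA4 63.2-fold and MSTN, the secreted inhibitor of muscle growth, 57.7-fold. PALMD rose 51.2-fold, HOXA2 45.3-fold and IGFBP5, a binding protein of insulin-like growth factors, 42.7-fold. Adjusted p-values of these 10 genes lay between 1.66e-07 and 3.40e-05.

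The largest fall was in MIR302C (probe set 16979114), a microRNA precursor gene in a cluster that is active in pluripotent cells. It went from 11.09 ± 0.076 to 3.20 ± 0.053, 237-fold lower (adjusted p = 1.66e-07). Its neighbours in the cluster fell with it, MIR302D 90.4-fold, MIR302A 78.2-fold, MIR302B 60.6-fold and MIR367 58.4-fold. ESRG, a long noncoding RNA of embryonic stem cells, fell 169.7-fold, and LIN28A, the RNA-binding protein that blocks let-7 maturation, 113-fold. L1TD1, an RNA-binding protein of pluripotent cells, fell 85.4-fold, the metallothionein MT1G 63.9-fold and ESRP1, an epithelial splicing regulator, 58.7-fold. In 17 of these 20 genes with the largest differences the dimmer group averaged under the lowest array median, so background signal sets part of each such fold.

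**Figure D1:**
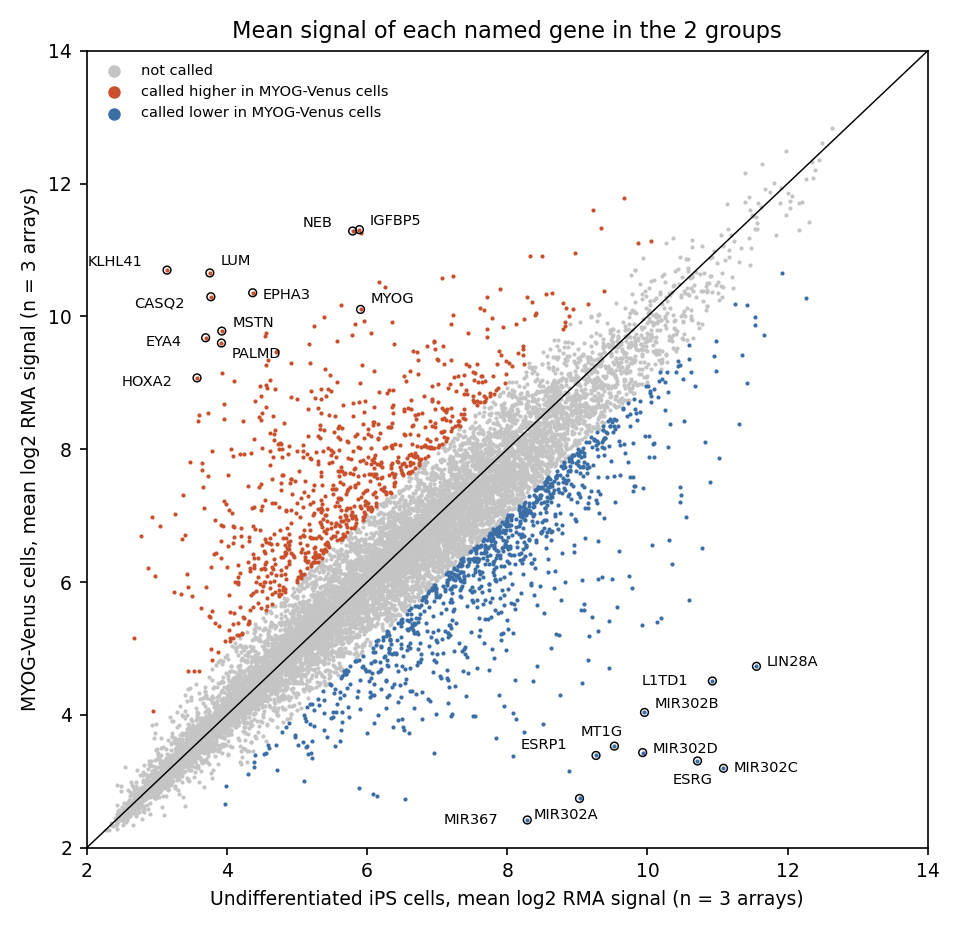
Mean log2 RMA signal of each named gene in undifferentiated iPS cells (x axis) and MYOG-Venus cells (y axis), over 3 arrays each, without Y-linked genes and XIST; colours mark the called genes, circles MYOG and the 20 genes with the largest differences, and the line equal signal. MYOG stands above the line at 10.11 against 5.91, and the 10 largest rises and 10 largest falls lie farthest from it.

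Among the 16 genes fixed for naming before the data were examined, 11 had a named probe set and 5 were not analysed here. All of the myogenic transcription factors among them rose. MYF6, which is active in maturing fibres, rose 30.5-fold from 4.10 ± 0.27 to 9.03 ± 0.17, and MYOD1, which commits cells to muscle, 4.11-fold from 5.64 ± 0.51 to 7.68 ± 0.24 (adjusted p = 3.70e-06 and 0.00142). MYF5, an early determination factor, rose 2.37-fold to a level of only 5.47 ± 0.090. The stricter limma test against 2-fold did not call MYOD1 (adjusted p = 0.0779) or MYF5 (adjusted p = 1). PAX3 and PAX7, transcription factors of muscle progenitors, rose 21.4-fold and 5.16-fold (adjusted p = 1.62e-06 and 4.81e-06). MYMK, the membrane protein that drives fusion of myoblasts, rose 24.5-fold (adjusted p = 4.08e-06). On the pluripotency side, NANOG fell 11.6-fold, SOX2 8.93-fold and the de novo DNA methyltransferase DNMT3B 29.1-fold, with adjusted p from 3.53e-06 to 6.54e-05. SOX2 still averaged 7.31 ± 0.42 in sorted cells. POU5F1 was read by a dim probe set that averaged 5.57 ± 0.61 in iPS cells and fell 2.66-fold (adjusted p = 0.0122), and without MYOG-Venus replicate 1 its adjusted p was 0.0522. The probe set of its pseudogene POU5F1P3, looked up after the values were seen, was bright in iPS cells at 10.55 ± 0.13 and fell 11.9-fold, and near-identical sequences leave open which transcript either probe set bound.

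**Figure D2:**
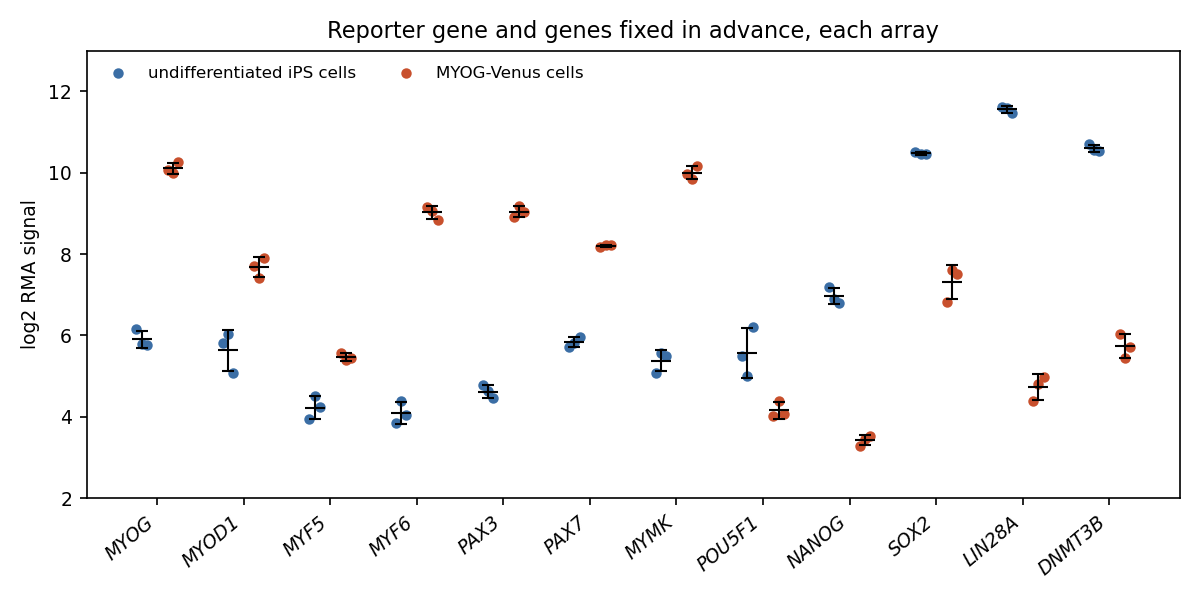
Log2 RMA signal (y axis) of MYOG and of the 11 measured genes fixed in advance; each point is 1 array, and black bars give the mean and SD of 3 arrays per group. Groups do not overlap for any of these genes. PAX7 rose from 5.83 to 8.20, and its values on MYOG-Venus replicates 2 and 3 were identical, which narrows its spread.

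A total of 31 gene lists fixed before the data were examined were tested with limma's camera, which asks whether a list stands higher or lower than other genes. 13 lists stood higher and 3 lower at an adjusted p under 0.05, and 7 of these 16 calls held with an estimated correlation between genes. These 7 were the pluripotency, myogenic regulator, muscle progenitor, sarcomere, calcium-handling, HOX and epithelial lists. For each of the 31 lists the numbers that rose and fell were equal whether adjusted over all probe sets or adjusted over the list alone, so each is given once. Members said not to have passed missed the adjusted p or the 2-fold minimum.

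Sarcomere genes made up the most strongly shifted list. Of 27 measured, 19 rose and 8 did not pass, with a median log2 difference of 2.98 (camera adjusted p = 1.78e-16). TTN, which encodes the giant elastic protein titin, rose 40.8-fold to 11.26 ± 0.095, and MYOZ2, a Z-disc protein, 30.1-fold. 27 of the 61 genes fixed for this list had a named probe set, and the rest were not analysed here. Calcium-handling genes rose with them, 8 of 16, while ORAI1, the pore of store-operated calcium entry, fell (camera adjusted p = 1.01e-05). STAC3, which couples the voltage sensor to calcium release, rose 24.6-fold, sarcalumenin (SRL) 14.6-fold and the release channel RYR1 6.70-fold.

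Of 21 myogenic regulators, 15 rose and 6 did not pass, with a median of 1.60 (camera adjusted p = 2.23e-11). MYOG, on whose reporter the cells were sorted, is among the 15 and entered that test. MEF2C, a partner of the MYOD family, rose 27.0-fold and the muscle methyltransferase SMYD1 22.6-fold. Of 20 muscle progenitor genes, 13 rose, 6 did not pass and the syndecan SDC4 fell, with a median of 1.54 (camera adjusted p = 2.80e-08). Beside PAX3 and MSTN, the adhesion molecule NCAM1 rose 23.5-fold and the homeobox gene MEOX2 14.3-fold. Myoblast fusion genes rose in 7 of 12 cases, among them MYOF at 8.58-fold, ADAM12 at 6.19-fold and CAV3 at 3.80-fold, and CD9 and DOCK5 fell. That list's camera adjusted p was 0.00292, and its adjusted p = 0.349 with an estimated correlation.

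Lists for later features of muscle were not called by camera. Of 6 neuromuscular junction genes, RAPSN, which clusters acetylcholine receptors, rose 6.02-fold and 5 did not pass (camera adjusted p = 0.421). Of 6 genes of the dystrophin complex, DMD rose 4.30-fold, CAV3 rose too, and 4 did not pass (camera adjusted p = 0.0875). Among 10 muscle metabolism genes, AMPD1, the muscle AMP deaminase, rose 6.09-fold and the heart and muscle cytochrome oxidase subunit COX6A2 2.83-fold, hexokinase HK2 fell 2.83-fold, and 7 did not pass (camera adjusted p = 0.403). These 3 lists had fixed members without a named probe set, with 6 of 17, 6 of 25 and 10 of 24 measured.

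**Figure D3:**
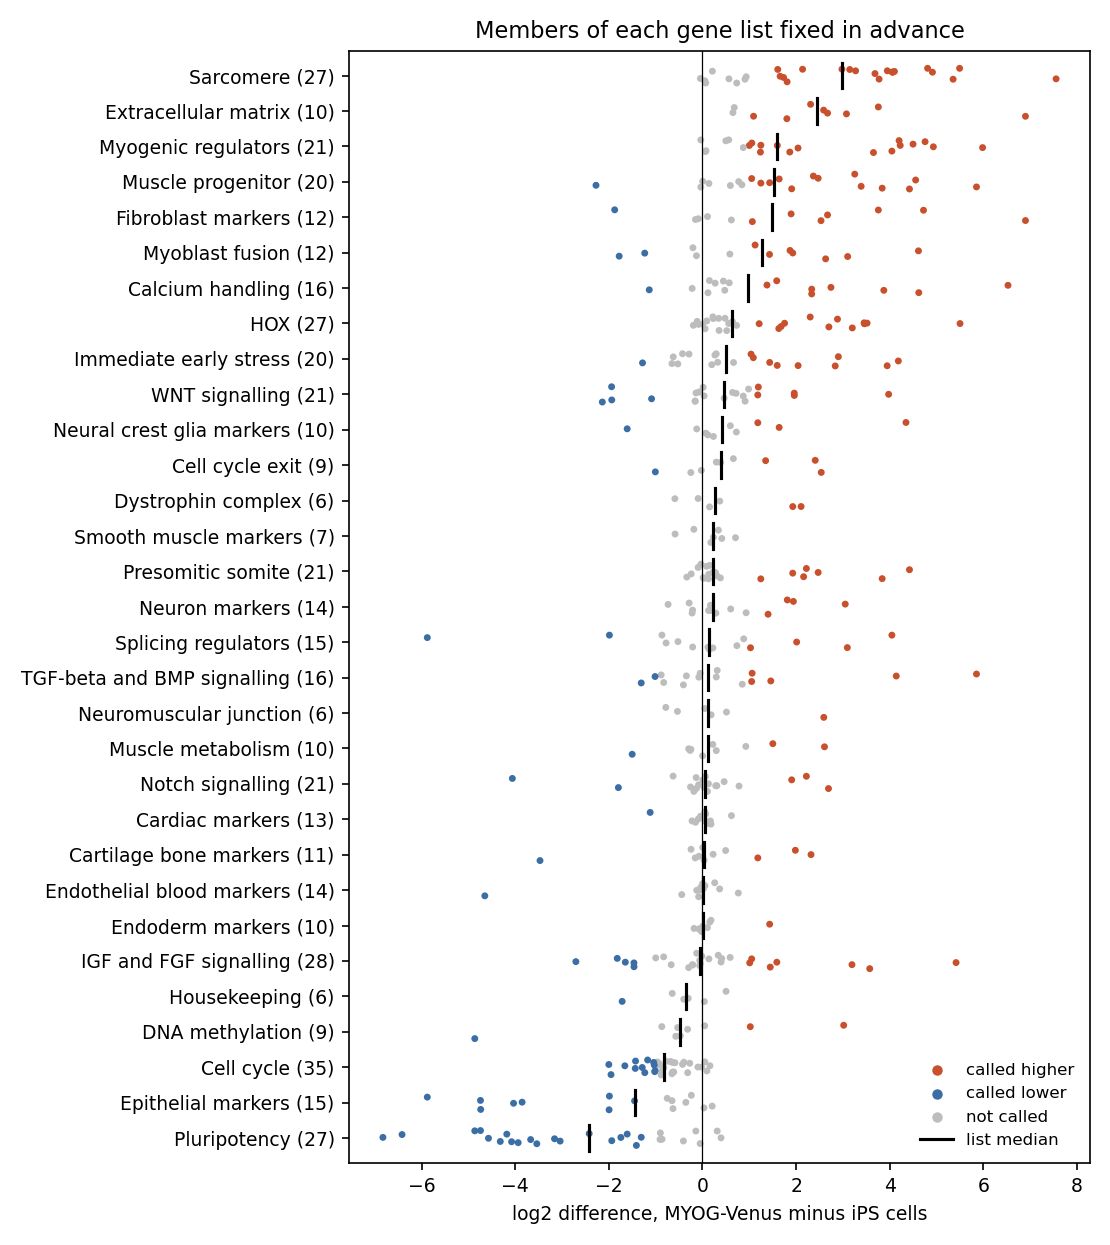
Log2 difference between MYOG-Venus and iPS cells (x axis, positive where higher in MYOG-Venus cells) of each measured member of the 31 gene lists, with the number measured beside each name; points are genes, spread vertically for display, and black bars are list medians. The sarcomere list has the highest median, 2.98, and the pluripotency list the lowest, −2.42.

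Of 27 pluripotency genes, 19 fell and 8 did not pass, with a median of −2.42 (camera adjusted p = 2.65e-11). Behind LIN28A, L1TD1 and DNMT3B, the adhesion molecule EPCAM fell 26.7-fold from 9.45 ± 0.12 to 4.71 ± 0.12. Epithelial markers fell in 8 of 15 cases and 7 did not pass, with a median of −1.45 (camera adjusted p = 1.24e-06), and 3 of the 15 also stand in another list. The tight junction claudins CLDN6 and CLDN7 fell 26.6-fold and 16.4-fold, beside ESRP1 and EPCAM.

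Regulators of splicing and of DNA methylation went both ways. Of 15 splicing regulators, ESRP1 and its paralog ESRP2 fell, 4 rose and 9 did not pass (camera adjusted p = 0.287). RBM24, a muscle splicing factor, rose 16.5-fold, and the muscleblind proteins MBNL2 and MBNL1 rose 8.53-fold and 4.03-fold. The median of this list was 0.15, and fry, which does not compare it with other genes, gave the opposite sign. Of 9 DNA methylation genes, DNMT3B fell, 6 did not pass, and TET2, which oxidises methylcytosine, rose 8.09-fold (camera adjusted p = 0.355). The methyl-CpG binding protein MBD2 rose 2.03-fold, and without iPS replicate 1, iPS replicate 3 or MYOG-Venus replicate 3 its log2 difference was 0.90, 0.97 or 0.99, short of 2-fold, as was the 0.99 with arrays centred.

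Cell cycle genes were moderately lower. Of 35 measured, 12 fell, 23 did not pass, and 16 of these 23 were lower at an adjusted p under 0.05 but by less than 2-fold. The list's median was −0.82 (camera adjusted p = 1.67e-08), with adjusted p = 0.118 with an estimated correlation. The 4 largest falls were in genes of S-phase entry and DNA replication. CDC6, which loads the replicative helicase, fell from 9.12 ± 0.045 to 7.12 ± 0.078. The helicase subunits MCM5 and MCM3 fell 3.87-fold and 3.16-fold, and cyclin E1 (CCNE1) 2.70-fold. Outside the naming rule, and looked up after the values were seen, MYBL2, BUB1, FOXM1, CCNB1 and CDC20 fell, with log2 differences of −1.23 to −1.01. TOP2A and MKI67, members of the same list looked up in the same way and among its 4 highest differences, did not pass. TOP2A averaged 10.64 ± 0.073 in iPS cells and 10.62 ± 0.22 in sorted cells (log2 difference −0.02, adjusted p = 0.928), a difference whose sign turned to 0.07 when quantile normalization was applied again. MKI67 averaged 9.15 ± 0.045 and 9.31 ± 0.12 (log2 difference 0.16, adjusted p = 0.193). Its log2 difference was 0.34 with quantile normalization applied again.

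Of 20 cell cycle exit genes fixed in advance, 9 were measured. The CDKN, BTG and GADD45 genes of the list were not analysed here, and the D cyclins CCND1, CCND2 and CCND3 were. Of the 9, 3 rose, 1 fell and 5 did not pass, with a median of 0.39. The camera adjusted p was 0.0369, and adjusted p = 0.364 with an estimated correlation. GAS1, a growth arrest gene, rose 5.80-fold, cyclin G2 (CCNG2) 5.31-fold and the retinoblastoma gene RB1 2.55-fold. Cyclin D1 (CCND1) fell 2.01-fold, and without iPS replicate 1, iPS replicate 2 or MYOG-Venus replicate 1 its log2 difference was −0.99, −0.96 or −0.92, and with quantile normalization applied again −0.85. The list's adjusted p was 0.0505 without iPS replicate 3, 0.0511 without MYOG-Venus replicate 2 and 0.0510 without MYOG-Venus replicate 3.

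HOX genes, which pattern the body axis, rose in 12 of 27 cases and 15 did not pass, with a median of 0.64 (camera adjusted p = 1.67e-08). After HOXA2, the largest rises were in HOXB9 at 11.4-fold, HOXB3, from 4.68 ± 0.089 to 8.14 ± 0.16, and HOXC4 at 10.9-fold. Genes of presomitic mesoderm and somites rose in 7 of 21 cases and 14 did not pass, with a median of 0.23 (camera adjusted p = 0.000404, and adjusted p = 0.0546 with an estimated correlation). The members with the largest rises were PAX3, MEOX2, DMRT2 at 5.54-fold and the Notch ligand DLL1 at 4.66-fold. TBX6, MSGN1, MESP1, MESP2 and HES7 of this list, looked up after the values were seen, did not pass. Their log2 differences lay between −0.24 and 0.28. 6 of the 21 also stand in another list.

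Members of signalling pathways rose and fell, and camera called none of the 4 pathway lists. The lists were covered unequally, with 21 of 22 Notch and 28 of 31 IGF and FGF genes measured. Of the TGF-beta and BMP genes 16 of 34 were measured, without the TGFB, receptor and ID genes. For WNT it was 21 of 36, without any WNT ligand gene, so these 2 results cover part of each pathway. Of 21 Notch genes, 3 rose, 2 fell and 16 did not pass (median 0.06, camera adjusted p = 0.338). Notch target genes split, as HEY2 fell 16.7-fold while HEY1 and HEYL rose 6.46-fold and 3.75-fold. Of 28 IGF and FGF genes, 7 rose, 5 fell and 16 did not pass (camera adjusted p = 0.625), with a median of −0.05 but a mean of 0.23. The growth factors IGF1 and FGF9 rose 11.9-fold and 9.14-fold, and FGF2, a factor of pluripotent cultures, fell 6.51-fold. Of 16 TGF-beta and BMP genes, 5 rose, 2 fell and 9 did not pass (median 0.12, camera adjusted p = 0.275). Beside MSTN, BMP5 rose 17.6-fold and BMP4 2.75-fold, and GDF3, a ligand of pluripotent cells, fell 2.48-fold. Of 21 WNT genes, 5 rose, 4 fell and 12 did not pass (median 0.46, camera adjusted p = 0.0744). The secreted antagonist FRZB rose 15.7-fold, LGR5 3.89-fold and LEF1 3.89-fold, and the receptor FZD5 fell 4.40-fold.

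Of 30 extracellular matrix genes fixed in advance, 10 were measured, without any collagen or laminin gene. Of these 10, 8 rose, with a median of 2.45. The camera adjusted p was 7.86e-08, and adjusted p = 0.143 with an estimated correlation. Beside LUM, the proteoglycan decorin (DCN) rose 13.5-fold, tenascin C (TNC) 8.43-fold and fibrillin 1 (FBN1) 6.37-fold. Fibroblast markers moved with them, as 7 of 12 rose, 4 did not pass and THY1 fell 3.67-fold, with a median of 1.48. The camera adjusted p of this list was 0.000181, and adjusted p = 0.123 with an estimated correlation. It was fixed with 20 markers, and its collagen genes, PDGFRA, PDGFRB, POSTN and FAP were not analysed here. OGN, a small proteoglycan, rose 26.4-fold, and 3 of these 12 markers also stand in the matrix list.

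Lists of neuron and of neural crest markers, cell types that such a culture can hold, were called higher with the preset correlation but not with an estimated one. Of 14 neuron markers, 4 rose and 10 did not pass, with a median of 0.23 (camera adjusted p = 0.0415, and adjusted p = 0.473 with an estimated correlation). DCX rose 8.27-fold, STMN2 3.84-fold, POU4F1 3.51-fold and MAP2 2.64-fold. The neuron list's adjusted p was 0.0529 without iPS replicate 1, 0.0582 without iPS replicate 3, 0.0818 without MYOG-Venus replicate 2 and 0.0510 without MYOG-Venus replicate 3. Of 10 neural crest and glia markers, 3 rose, FOXD3 fell 3.05-fold and 6 did not pass, with a median of 0.41 (camera adjusted p = 0.0305, and adjusted p = 0.355 with an estimated correlation). SNAI2, a factor of migrating mesenchyme, rose 20.3-fold and NGFR, which also stands in the progenitor list, 3.11-fold. SOX9 rose 2.27-fold (adjusted p = 0.0148), and its call was lost in 5 of the 6 fits that left out 1 array. Those fits had adjusted p = 0.0515, 0.0571 and 0.0586 without iPS replicates 1, 2 and 3 and 0.0578 without MYOG-Venus replicate 1, and a log2 difference of 0.92 without MYOG-Venus replicate 3.

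Of 11 cartilage and bone markers, 3 rose, 1 fell and 7 did not pass (median 0.03, camera adjusted p = 0.271). SOX5 and SOX6 rose 4.99-fold and 3.95-fold beside SOX9, and chondromodulin (CNMD) fell 11.1-fold. For smooth muscle, all 7 markers missed the 2-fold minimum or the adjusted p in limma (median 0.23, camera adjusted p = 0.243). TAGLN differed most, by 0.71 on the log2 scale (adjusted p = 0.000715), and in total 3 higher markers and 1 lower marker passed the adjusted p alone. Of 13 cardiac markers, 12 did not pass and TNNI3, the cardiac troponin I, fell 2.17-fold (median 0.05, mean −0.03, camera adjusted p = 0.610). Without MYOG-Venus replicate 3, TNNI3 had a log2 difference of −0.94. Of 14 endothelial and blood markers, 13 did not pass and KDR, a receptor of vascular endothelial growth factor, fell 25.1-fold from 8.52 ± 0.10 (median 0.01, mean −0.28, camera adjusted p = 0.787). That median turned to −0.02 with arrays centred and −0.01 with quantile normalization applied again. Of 10 endoderm markers, 9 did not pass and the chemokine receptor CXCR4, which the progenitor list also holds, rose 2.70-fold (camera adjusted p = 0.453).

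Immediate early and stress genes rose in 9 of 20 cases, FOSL1 fell and 10 did not pass, with a median of 0.49. The camera adjusted p was 0.00178, and adjusted p = 0.243 with an estimated correlation. EGR1 rose 18.2-fold to 10.45 ± 0.17, FOS 15.4-fold, JUN 7.47-fold and FOSB 7.13-fold. Of 6 housekeeping genes, HPRT1 fell 3.28-fold and 5 did not pass, with a median of −0.35 (camera adjusted p = 0.271). GAPDH, looked up after the values were seen, had a log2 difference of −0.40 (adjusted p = 0.00374).

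The labels describe sorting of the differentiated cultures, with gates set against undifferentiated ones. They do not say whether the undifferentiated cells used for the arrays were sorted too. The line is named for the undifferentiated cells alone, so handling and line cannot be told apart from the group. No array held unsorted cells of the differentiated cultures or their cells without Venus. Differences tied to MYOG-expressing cells therefore cannot be told apart from those of 3 weeks of differentiation in general. With 3 arrays per group, their number limits the precision, and the median standard error of a log2 difference was 0.0927.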

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

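The fit of the named probe sets alone was chosen after the data were seen, and the other alternatives before. Counts depended mainly on the fold minimum: without one, 2441 genes were higher, 3623 lower and 15000 probe sets called, and with limma's treat against 2-fold the counts were 469, 417 and 1902, by construction a looser and a stricter rule. The named probe sets alone gave 1905 calls, since fewer were tested. Median centring gave 796 higher and 1043 lower genes, a further quantile normalization 898 and 839 (higher share 51.7% against 45.4%), the probe sets above the 50th percentile by mean 798 and 948, the trend and robust spread model 830 and 997, and the mean of a gene's probe sets 819 and 982. Leaving out 1 array gave 815 to 838 higher genes, 954 to 1077 lower and 4456 to 4828 probe sets; both 815 and 1077 came without MYOG-Venus replicate 3, the array that stood apart. 1711 to 1762 of the 1827 called genes kept their call in those fits. Deviations of same-numbered samples from their group means correlated at r = −0.044, −0.058 and −0.019, which gave no sign of pairing by number. The labels do not say whether the samples were matched. With the replicate block 830 genes were higher, 996 lower and 4617 probe sets called, and no list or named gene changed its call. With an estimated correlation the calls of myoblast fusion (0.349), cell cycle (0.118), cell cycle exit (0.364), presomitic and somite (0.0546) and extracellular matrix (0.143) genes were lost, and on ranks that of cell cycle exit (adjusted p = 0.0754); the adjusted p of cell cycle exit ranged from 0.0169 to 0.0511 with 1 array left out. Fry, which asks another question, called neuromuscular junction (0.0344), dystrophin complex (0.000148), muscle metabolism (0.0284), IGF and FGF (0.0313), TGF-beta and BMP (0.0102) and WNT (0.0255) genes higher, and splicing (0.000258) and DNA methylation (0.00123) genes lower. Among marker and quality lists, those of neurons, neural crest, fibroblasts and immediate early genes lost their calls with an estimated correlation; the neuron call was also lost with quantile normalization applied again (0.0634), above the 50th percentile (0.0640) on ranks (0.0575) and in 4 of the 6 fits without 1 array (highest 0.0818), and the neural crest call above the 50th percentile (0.0537). Fry called cartilage and smooth muscle markers higher (0.0177 and 0.000227) and endothelial and housekeeping lists lower (0.000552 and 0.00168). Beyond these constructions, the cause was not tested. Of 106 named genes, 104 had a value in all 15 settings and 88 of these kept their side of the threshold; AMPD1 and DMRT2 had none above the 50th percentile and kept theirs in the other 14 settings. 15 lost their call with treat, MYOD1, MYF5, POU5F1, COX6A2, RB1, CCND1, MBD2, BMP4, GDF3, MAP2, NGFR, FOXD3, SOX9, TNNI3 and CXCR4, and of these POU5F1, CCND1, MBD2, SOX9 and TNNI3 in other settings too; TAGLN gained one without the fold minimum, and no direction was reversed. Dropping probe sets by ID suffix was not run, since the IDs are plain numbers. Signal over background limits the folds of dim genes.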

Other observations

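The tests of explanations in this part, its gene families, and its genes outside the naming rule were chosen after the values were seen; camera on the fixed lists was planned. Of 1072 measured microRNA precursor genes, the MIR302 and MIR367 genes included, 38 rose and 22 fell in limma, a smaller share than the 830 and 997 of all 14884 genes. The difference in share was not tested, and these genes were dim, with medians of 3.82 in iPS cells and 3.85 in sorted cells. Without the let-7 genes, the family of 1062 was not called by camera (adjusted p = 0.138, and adjusted p = 0.756 with an estimated correlation). The muscle microRNA genes MIR133B and MIR206 rose 15.3-fold and 6.29-fold (adjusted p = 1.63e-06 and 0.000275). Of 10 let-7 genes, MIRLET7C and MIRLET7A2 rose 15.1-fold and 5.58-fold and 8 did not pass. LIN28A, which blocks let-7 maturation, fell. LIN28B stayed bright, at 9.53 in iPS cells and 8.67 in sorted cells (log2 difference −0.86, short of 2-fold). A link between the LIN28 and let-7 genes was not tested. MIR99AHG, the host transcript of MIRLET7C, rose 28.5-fold. MIR18B, MIR20B and MIR19B2 of the miR-106a cluster fell 9.70-fold, 10.3-fold and 13.9-fold. Array signal at such a locus does not separate precursor, host transcript and mature microRNA.

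Further transcription factors rose, all outside the fixed lists except TBX18, a member of the presomitic and somite list. All 3 measured MEIS genes rose, MEIS1 21.4-fold, MEIS2 20.2-fold and MEIS3 2.20-fold; their proteins bind DNA together with HOX proteins. Of 4 EBF genes, EBF2 rose 35.8-fold, EBF3 12.4-fold and EBF1 4.16-fold. Of 13 TBX genes, TBX15 rose 21.1-fold, TBX18 4.47-fold and TBX3 3.95-fold, and 10 did not pass. PRL, the hormone prolactin, rose 36.7-fold from 4.56 ± 0.19 to 9.75 ± 0.073 (adjusted p = 7.44e-07). Among 193 gene families formed by symbol stem, camera called 15. None of these calls held with an estimated correlation, a test that rests on few degrees of freedom with 6 arrays. The mitochondrial ribosomal proteins of the large subunit had a median of −0.51 over 48 genes (adjusted p = 9.99e-06, and adjusted p = 0.678 with an estimated correlation). Of these 48, 1 fell, and of 25 genes in the small subunit family, 4 fell. A wider set of 78 genes with such names held loci outside both families. In it 5 fell and 47 more were lower by less than 2-fold at an adjusted p under 0.05. Metallothioneins, which bind zinc and copper, fell in 5 of 11 cases, among them MT1H 26.0-fold, MT1X 8.85-fold and MT2A 2.74-fold beside MT1G. The family of 11, which includes MT3 and MT4, had a median of −0.75, its 9 MT1 and MT2 genes had one of −1.45, and the family test gave adjusted p = 0.0269, and adjusted p = 0.703 with an estimated correlation.

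Of the 10 ways to split 6 arrays into 3 and 3, 1 gave as many called probe sets as the real one, which was the real split itself with 4615, and the highest of the others gave 1. With 10 splits no share under 0.05 can be reached.

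Cell cycle transcripts kept a median of 56.5% of their iPS level in cells sorted on a reporter of terminal differentiation. Undifferentiated cells in the sorted fraction are argued against, since 14 pluripotency genes with an iPS mean of at least 9 kept a median of 6.23% (quartiles 3.86% and 11.9%), below the quartiles of 48.7% and 70.5% for the cell cycle genes. A compressed signal of bright probe sets stays open, since across the 35 genes, which are not independent replicates, mean signal over all arrays and log2 difference had Spearman rho = 0.17 (permutation test, 100000 resamples, p = 0.340), and iPS mean signal in place of that mean gave rho = −0.09. Cycling muscle progenitors in the sorted fraction remain open as a hypothesis, and PAX7, with a log2 difference of 2.37, is consistent with them. The arrays cannot show whether PAX7 and MYOG transcripts lay in the same cells.

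Connective tissue transcripts such as LUM, OGN and DCN rose with the muscle genes. A mixture of all other cell types of the culture is not decided. The 14 endothelial and blood markers had a median of 0.012 (quartiles −0.077 and 0.050), narrowly below the quartiles of 0.058 and 2.94 for fibroblast markers. That list was taken as the one with the lowest upper quartile among 7 lists without the epithelial one. None of its markers rose by 2-fold. ERG and RUNX1 were higher in limma at an adjusted p under 0.05, with log2 differences of 0.77 and 0.37. CD34 was lower at that threshold by less than 2-fold, and KDR fell. The list does not speak for other types. Camera called neuron and neural crest markers higher, though not with an estimated correlation (adjusted p = 0.473 and 0.355). Fibroblast-like cells in the sorted fraction may account for the rise of connective tissue transcripts. Only 12 of the 20 fibroblast markers fixed in advance were measured, without the collagen genes. The 8 fibroblast markers besides the 4 with the largest rise had a median of 0.36. Of these, 3 rose and THY1 fell, and they decide nothing. The sort on Venus would remove cells without the reporter, 3 of the 12 markers also stand in the matrix list, and LUM averaged 10.66 ± 0.22 in sorted cells. Expression of these genes by the muscle cells themselves stays open and was not tested.

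Immediate early transcripts such as EGR1 and FOS rose in sorted cells. A heat shock type of stress is not decided, since only 3 heat shock genes were measured and they went both ways. Their median log2 difference was −0.53 (range −0.62 to 0.66), and none reached 2-fold. The lower ones, HSPA1A and HSPA1B, are closely related genes and may not be separate readings. Dissociation and sorting of 1 group only may account for the rise, but the labels do not say whether undifferentiated cells were sorted too, the whole list had a median of 0.49 with members going both ways, and handling cannot be told apart from cell type. A difference between muscle and pluripotent cells in these genes stays open and was not tested.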
